A study of Mus musculus with 31 samples.

How the data were processed

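The samples are mouse (strain C57BL/6 per the labels) RNA-seq libraries of 3 kinds. DN1 and DN3 thymocytes, 2 early stages of T cell development, were cultured on OP9-DL1 stromal cells with IL-2, IL-7 and SCF. The cells carried a tamoxifen-inducible Cre (R26-CreERT2) and a tdTomato reporter, either with floxed E2A and HEB alleles (called floxed here) or without them (called control). E2A is the gene Tcf3 and HEB the gene Tcf12. 4-hydroxytamoxifen (4-OHT) was added on day 4, and libraries were made on day 4 before it and, from sorted tdTomato-positive cells, on days 5 and 7. The labels of the DN1 day 7 samples give day 7 for 4-OHT where the design text gives day 4, and day 4 was used. The other libraries come from group 2 innate lymphoid cells (ILC2) isolated directly from the thymus of mice with floxed E2A and HEB alleles and a plck-Cre transgene (called dKO after their titles), from the lung of dKO mice, and from the lung of mice carrying the plck-Id1 transgene. The genotype labels of 2 of the 3 Id1 lung samples read plck-Id2 and plck-Id3, while their titles give Id1 with replicate numbers 2 and 3. They were grouped by title, and Id1 was the transgene RNA checked. Samples of mesenteric lymph nodes named in the design text are not analysed here, since no values for them are among the files.

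The deposited values are raw counts, one column per library and one row per Ensembl gene, in a thymus table of 26 libraries and a lung table of 5. Each table holds 48881 genes, of which 33530 have a count in the thymus table and 39747 in the lung table. The values are whole numbers with different totals per library. The submitters' processing notes name the genome build mm10 and DESeq2, with no versions. The aligner, the counting program and the annotation release are not given in the sources used here. RNA was total RNA extracted with Trizol and libraries followed standard Illumina protocols per the labels. Gene names, biotypes and positions (1-based, mm10) were taken from GENCODE M21, which held 48664 of the gene IDs. The other 217 kept their IDs. Of the genes listed in advance, Trgc1, Trgc2, Trgc4 and Scart2 have no gene of that name in this annotation.

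Every one of the 12 culture groups, the thymic ILC2 group and the lung dKO group has 2 libraries, and the lung Id1 group has 3. Groups and replicates were taken from the titles. Nothing in the labels says whether replicates are separate animals or separate cultures, so each p measures the spread between these samples. Replicate letters a and b mark floxed cultures and c and d mark control cultures on every day, but no source says that a letter is the same animal on all days. Counts per library totalled 5908459 to 10692186 in the cultures, 4818443 and 5669876 in thymic ILC2, 3695522 and 5627406 in lung dKO and 9671437 to 13065445 in lung Id1. At 5908459 counts, 1 CPM (counts scaled to the library total) is about 6 reads, so genes under a few CPM were near the limit of what these libraries can show.

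Differential expression was tested with edgeR 4.0.16 under R 4.3.3. The 24 culture libraries were fitted together with 1 mean per group, and so were the 5 lung libraries. The thymic ILC2 libraries were fitted with all 26 libraries of their table. Genes were kept with filterByExpr (minimum count 10, by group), which left 15172 genes in the cultures, 16391 in the table with thymic ILC2 and 19371 in the lung. Libraries were scaled with TMM, and quasi-likelihood tests were adjusted by Benjamini-Hochberg over the tested genes of each comparison. A gene passed at an adjusted p (FDR) under 0.05. Residual degrees of freedom were 12 in the cultures and 3 in the lung. The common biological coefficient of variation was 0.138 in the cultures, 0.151 with thymic ILC2 and 0.706 in the lung. Fold changes are log2 values from this fit, written with their standard error (log2 change over the square root of F). A fold change against a group with no counts is given as a lower bound, with a floor of 3 counts over that group (the upper 95% limit of a count of 0). Against 1 to 3 counts it is given as a ratio of pooled CPM with a 95% interval that covers counting error only.

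The 16 comparisons were fixed with their tests before the data were examined: floxed against control at days 4, 5 and 7 for DN1 and DN3, the change of that difference from day 4 to day 7, control cultures at day 7 against day 4, the difference between DN1 and DN3 in the response at days 5 and 7, DN1 against DN3 controls at day 4, thymic ILC2 against DN1 and DN3 floxed cultures at day 7, and lung dKO against lung Id1. The genes named in the report follow a rule of the same date. It takes the 10 largest positive and 10 largest negative log2 changes that passed in the day 5, day 7 and lung comparisons, and 5 each way elsewhere. A gene also needed a mean CPM of at least 20 in the higher group and no overlap between the libraries of the groups. Predicted genes and V, D and J segments were left out. The targeted genes and Id1, Id2 and Id3 were always included, and each list added up to 4 members that passed and 2 abundant members that did not. Genes named outside the rule are stated as such. The report prints only part of the genes that the rule gives, and many were left out. What was left out of the text is not reported here, while tests of whole lists include it.

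The 20 gene lists, also fixed in advance, are E proteins and Id proteins, ILC2 transcription factors, ILC2 receptors and surface molecules, type 2 cytokines and effectors, antigen receptor recombination and pre-TCR signalling, the Notch pathway, early progenitor genes, NK cell and ILC1 genes, ILC3 genes, gamma-delta T cell genes, alpha-beta TCR constant genes, markers of myeloid cells, of mast cells and basophils, of B cells, of stromal cells and of lung epithelium, endothelium and alveolar macrophages, cell division genes, p53 targets, interferon response genes, and immediate early and heat shock genes. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison. A set of 200 genes higher and a set of 200 genes lower in thymic ILC2 than in day 4 control cultures (log2 over 2) was tested in the same way at days 5 and 7.

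The alternatives tried were RLE scaling, DESeq2 1.42.0, no filter on low counts, a further threshold of 1 on the absolute log2 change, fits of the compared libraries alone, leaving out each library in turn, a block by replicate name, camera with an estimated correlation, fry, and 100 genes in place of 200. Further alternatives were added after the data were seen: without X and Y genes, without day 4 libraries, without mitochondrial rRNA and Gm10800 family genes, protein-coding genes only, a mean CPM of at least 20, and day 5 controls as the reference of the gene sets. Where leaving out a library left a group with 1 library, that library was assumed to vary like those of the other groups.

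The tests were checked on simulated counts with known changes. Each gene had the dispersion of the real table and 1 mean for all groups, averaged over the real groups. Apart from the changed genes no gene differed. In the real data 12079 of 16391 genes differed between thymic ILC2 and DN1 cells, and 3499 of 19371 in the lung. How scaling and false calls behave where so many genes differ was therefore not checked. With 100 genes changed 2-fold and 100 changed 4-fold in 1 culture group of 2 libraries, edgeR found 46 and 83 of them, and 6 of its 135 calls were false. For the thymic ILC2 comparison it found 33 and 68. For the lung comparison it found 0 and 15, with 4 false among 19 calls, so in the lung most 2-fold changes would have been missed. DESeq2 on the lung simulation found 2 and 22, with 46 false among 70 calls. A changed set of 20 genes was found by camera in all 3 simulations and 0 of 45 unchanged sets were called. Genes were drawn independently of each other and unchanged sets at random. The simulation therefore cannot show how often the preset correlation gives false calls for lists whose genes move together. With an estimated correlation the lung set was missed (p = 0.568).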

Results

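RNA-seq counts were collected from 31 libraries: DN1 and DN3 thymocyte cultures with floxed E2A and HEB alleles or without them on days 4, 5 and 7 (12 groups, n = 2 each), ILC2 of dKO thymus (n = 2), ILC2 of dKO lung (n = 2) and ILC2 of Id1 transgenic lung (n = 3). Totals ranged from 3695522 to 13065445 counts per library. E proteins drive early T cell genes, and the cultures ask what thymocytes express once E2A and HEB are deleted. All ± values are standard errors of log2 changes, and all adjusted p values are from edgeR unless camera, a test of gene lists, is named. Genotype and sex went together in the cultures: Xist, expressed in females, ranged from 588 to 1900 CPM in floxed libraries and from 4.55 to 71.4 in controls, and Y-linked genes summed to 0.508 to 26.7 CPM against 76.4 to 191. Markers of stromal cells summed to 2750 to 13800 CPM on day 4, when no cells were sorted by tdTomato, and to 67.3 to 275 CPM on days 5 and 7.

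Transcripts of the targeted genes Tcf12 (HEB, chromosome 9, 71842688 to 72111871, minus strand) and Tcf3 (E2A, chromosome 10, 80409514 to 80433647, minus strand) were compared first, since the cultures were made to delete them. Tcf12 was lower in floxed cells from day 5 on, and Tcf3 passed on day 7. Gene counts include the exons outside the floxed region, so they need not reach 0. In DN1 controls Tcf12 averaged 171, 215 and 273 CPM on days 4, 5 and 7, against 203, 109 and 108 in floxed cells. In DN3 controls it averaged 483, 501 and 507 CPM, against 460, 313 and 160 in floxed cells. Its log2 change was 0.24 ± 0.10 on day 4 (adjusted p = 0.961), -0.99 ± 0.10 on day 5 (8.87e-06) and -1.33 ± 0.10 on day 7 (6.53e-08) in DN1. In DN3 it was -0.07 ± 0.10 (0.892), -0.68 ± 0.10 (0.00021) and -1.66 ± 0.10 (5.05e-09). Tcf3 averaged 64.8, 87.6 and 86.2 CPM in DN1 controls and 55, 49.9 and 27.6 in DN1 floxed cells, and 93.8, 112 and 97 against 70.2, 62.2 and 24 in DN3. Tcf3 means were below controls on every day, and the change passed on day 7 alone, in DN1 (-1.64 ± 0.37, adjusted p = 0.00326) and DN3 (-2.03 ± 0.38, 0.000475), where the floxed replicates spread over a standard deviation of 15.2 and 12.6 CPM. The ILC2 of dKO thymus (plck-Cre with floxed alleles) had 276 CPM of Tcf12, which lies between the DN1 and DN3 controls, and 8.98 of Tcf3, below every culture group, in libraries of another kind. Those of dKO lung had 120 and 3.06, against 197 and 9.72 in Id1 lung.

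**Figure D1:**
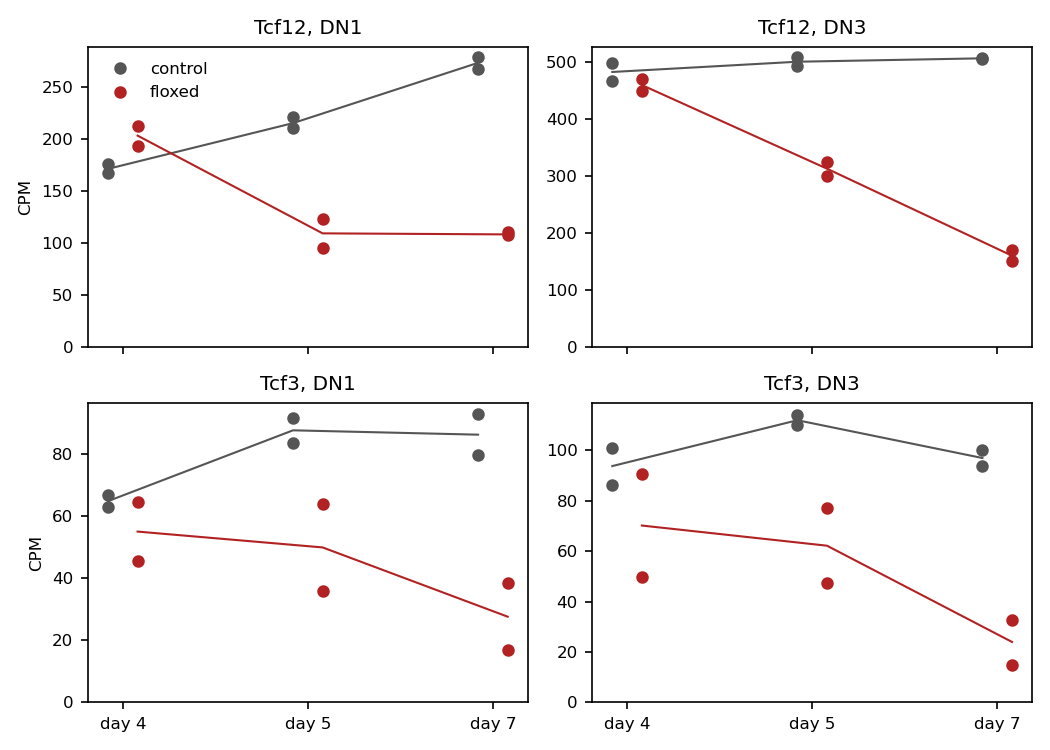
CPM of Tcf12 (top) and Tcf3 (bottom) in DN1 (left) and DN3 (right) cultures by day, floxed in red and control in grey; each point is 1 library (n = 2 per group) and lines join group means (Tcf12 in DN3 on day 7: 160 floxed, 507 control).

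On day 4, before 4-OHT, the DN1 comparison asks how far the cultures already differed. Xist was higher in floxed DN1 cells by 4.58 ± 0.54 (615 against 25.2 CPM) and Ddx3y, on the Y chromosome, lower by -2.27 ± 0.33 (9.36 against 47.8 CPM; n = 2 per group). Rps13-ps1, a pseudogene whose reads can belong to its parent gene, was higher (1.04 ± 0.10), and so was the paralog Rps3a2 (0.80 ± 0.11). Rpl29, which has close pseudogenes, was lower (-0.77 ± 0.09), and the source of reads for these genes is uncertain. In all, 16 of 15172 genes passed (9 higher, 7 lower), and 728 had an unadjusted p under 0.05. The number was 38 without floxed replicate b, 9 without control c and 8 without control d, and DESeq2 gave 45. Skap1 (1.53 ± 0.25) and Acss1 (0.97 ± 0.17) passed with all libraries and no longer without control d (adjusted p = 0.424 and 0.15) or control c (0.0591 and 0.386), and Skap1 and Acss1 also without floxed a (0.178 and 0.468). Rps3a3 was lost without any of the 4 libraries. No member of a gene list passed. Of the lists, 7 were nonetheless called by camera in the direction of floxed cells, none with an estimated correlation: ILC2 receptors and surface molecules (adjusted p = 2.19e-06, 0.126 with an estimated correlation), gamma-delta T cell genes (3.3e-06, 0.126), recombination and pre-TCR genes (4.18e-05, 0.311), ILC2 transcription factors (0.000141, 0.193), immediate early genes (0.000141, 0.126), cell division genes (0.00311, 0.179) and myeloid markers (0.00633, 0.367). Among the members of these 7 lists, adjusted over the list alone, 3 ILC2 transcription factors, 2 receptors, 4 gamma-delta genes and 1 myeloid marker were higher. The most abundant Notch pathway gene, Bcl11b, was near the threshold (0.57 ± 0.12, adjusted p = 0.0767).

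One day after 4-OHT, the day 5 comparison of DN1 cells asks for the first changes. Rora, a transcription factor of ILC2, rose by 4.18 ± 0.42 (153 against 8.38 CPM in controls; n = 2 per group, adjusted p = 6.59e-06). The chemokine receptors Ccr2 (3.21 ± 0.34; 81 against 8.74 CPM) and Cx3cr1 (2.99 ± 0.28; 71.3 against 9) rose, as did Fam129a (2.90 ± 0.30), Sh2d1a (3.44 ± 0.52) and Auts2 (2.90 ± 0.45). Cd3g fell by 2.63 ± 0.27 (6.23 against 38.6 CPM), and Fbp1 (-3.72 ± 0.43), Ndrg1 (-3.41 ± 0.32), Khdc1a (-2.77 ± 0.30), Mt2 (-2.61 ± 0.34), Tspan2 (-2.56 ± 0.30) and Cpne2 (-2.43 ± 0.32) fell with it. Il4 had no counts in controls and was at least 6.07-fold higher in floxed cells (1.29 CPM). The sex-linked genes Xist (6.82 ± 0.61) and Ddx3y (-6.43 ± 0.46) passed in the direction of the sexes of the groups, as did Uty and Eif2s3y, each with 2 counts in floxed cells (ratios of 227, 62.3 to 1880, and 167, 45.9 to 1390, lower). Of 15172 genes, 388 rose and 373 fell, 761 in all, with 225 without floxed replicate b, 281 without control c and 275 without control d.

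By list, 6 of 13 ILC2 transcription factors rose in DN1 on day 5 and 3 fell (7 and 3 adjusted over the list alone), with Rora above, Zbtb16 at 2.77 ± 0.40, Maf at 2.60 ± 0.34 and Lmo4 at 2.26 ± 0.23 (794 against 165 CPM). Gfi1, Ets1 and Bhlhe40 fell, against the rest of the list, and Id2 did not pass (0.03 ± 0.21). The list was called by camera (adjusted p = 1.08e-05, adjusted p = 0.155 with an estimated correlation). Camera had called this list and that of immediate early genes higher in floxed cells on day 4 already, before 4-OHT. Recombination and pre-TCR genes had 5 of 18 lower and 0 higher (6 adjusted over the list alone; 2.18e-05, adjusted p = 0.374 with an estimated correlation), and Lck and Lat did not pass. Notch pathway genes had 3 of 9 lower and 1 higher (5 and 1 adjusted over the list alone; 0.00447, adjusted p = 0.127 with an estimated correlation), led by Notch1 (-1.52 ± 0.19; 64.6 against 185 CPM). The higher one was Tcf7, against the direction of its list (0.67 ± 0.15), and it did not pass without floxed replicate b (adjusted p = 0.101), control c (0.121) or control d (0.0907). Immediate early and heat shock genes had 5 of 9 higher (6 adjusted over the list alone; 1.34e-06, adjusted p = 0.0703 with an estimated correlation), with Dusp1 at 1.97 ± 0.25. Fos and Fosb, in the same list, were lost without floxed b (0.0722 and 0.0838) or control d (0.0921 and 0.135). Of the E protein and Id list Tcf12 and Lyl1 (-1.74 ± 0.28) fell and Id3 rose (1.11 ± 0.17; 147 against 68.4 CPM), and the list, which holds the targeted genes, was called lower (0.0416, adjusted p = 0.155 with an estimated correlation). Of ILC2 receptors 4 rose and 1 (Il7r) fell among 17, without a list call (0.255), and Icos (2.62 ± 0.51) and Cysltr1 (2.09 ± 0.45) were lost without floxed replicate b (0.184 and 0.289) or control c (0.0792 and 0.0984), Cysltr1 also without control d (0.0909). Il9r (1.56 ± 0.30) was lost without floxed b or control c as well (0.118 and 0.0877). Other calls counted here were lost without single libraries. Whichever of the 4 was left out, Dntt (adjusted p = 0.113 to 0.206) and Notch3 (0.121 to 0.245) did not pass. Ptcra did not pass without floxed a (0.0785), floxed b (0.137) or control c (0.164), and Rag1 (0.0526) and Il7r (0.0674) not without floxed b. Nrarp and Gata3 were lost without floxed b (0.221 and 0.266), control c (0.0845 and 0.0611) or control d (0.0722 and 0.102). No stromal marker passed, 1 of 12 myeloid markers rose (Ctss, 1.87 ± 0.49), and Cdkn1a was the 1 of 10 p53 targets that fell (-0.81 ± 0.14). Cell division genes had 0 of 17 past the threshold with edgeR (0 adjusted over the list alone).

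By day 7 the DN1 difference took in more genes, with Rora, Maf and Lmo4, higher since day 5, among them. Icos rose by 4.87 ± 0.45 (353 against 12.1 CPM; adjusted p = 5.06e-07, n = 2 per group), Rora by 3.59 ± 0.37 (581 against 48.4), Maf by 3.56 ± 0.33 (800 against 67.7), Lmo4 by 3.33 ± 0.24 (2190 against 218) and Id2 by 2.34 ± 0.21 (719 against 142). Il13 rose by 6.31 ± 0.79 (25.2 against 0.3 CPM). Cd3g fell by 4.78 ± 0.29 (2.95 against 81 CPM), Dntt by 4.42 ± 0.43 (12.9 against 277) and Notch1 by 2.77 ± 0.20 (37.5 against 257). In all, 1848 genes rose and 1564 fell, 3412 of 15172, and 798 when these 4 libraries were fitted alone. The number was 5803 without floxed replicate a, 1688 without floxed b, 1879 without control c and 1862 without control d. Of the 388 and 373 genes that rose and fell on day 5, 280 and 252 did so on day 7, in other libraries.

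Among ILC2 transcription factors in DN1 on day 7, 9 of 13 rose and 4 fell (the same adjusted over the list alone; camera adjusted p = 7.34e-08, 0.0339 with an estimated correlation). Gfi1, Ets1, Pparg and Bhlhe40 were the ones that fell. Rxrg had 1 count in controls and a ratio of 395 (95% interval 70.4 to 15600). Receptors and surface molecules had 6 of 17 higher and 1 lower (8 and 1 adjusted over the list alone; 5.52e-05, adjusted p = 0.0857 with an estimated correlation), Ramp1 being the lower one. Camera had called this list higher in floxed cells on day 4 already, before 4-OHT, and did not call its change from day 4 to day 7. The lists of ILC2 transcription factors and of immediate early genes had been called higher on day 4 too. Camera called their change from day 4 to day 7 (adjusted p = 0.000222 and 0.0056), neither with an estimated correlation. Cysltr1 (3.25 ± 0.39), Tnfrsf18 (2.61 ± 0.35) and Il18r1 (2.34 ± 0.39) rose beside Icos, while Il2ra stayed level (-0.14 ± 0.10; 1150 against 1260 CPM). Of 4 tested type 2 cytokines and effectors 3 rose (0.000647, 0.0339 with an estimated correlation), Il13, Lta (2.18 ± 0.26) and Il4, the last not passing without control replicate d (2.54, adjusted p = 0.0646). Of 18 recombination and pre-TCR genes 8 fell and 0 rose (9 and 1 adjusted over the list alone; 3.7e-09, adjusted p = 0.0709 with an estimated correlation), Rag1 by 4.30 ± 0.50 and Rag2 by 3.97 ± 0.57. Of 9 Notch pathway genes 5 fell and 1 rose (7 and 1 adjusted over the list alone; 2.39e-06, 0.00582 with an estimated correlation), among them Notch3 (-2.36 ± 0.35), Nrarp (-1.34 ± 0.20) and Hes1 (-1.30 ± 0.23), while Dtx1 rose and Tcf7 did not pass. In the E protein and Id list 6 fell and 1 rose (7 and 1 adjusted over the list alone; 1.92e-06, 0.00356 with an estimated correlation), with Lyl1 at -3.62 ± 0.33, Id3 at -1.59 ± 0.17 and Id2 as the one that rose. That list holds the targeted Tcf12 and Tcf3, which fell by design, so part of its call was fixed in advance.

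Early progenitor genes had 6 of 13 lower and 2 higher in DN1 on day 7 (9 and 2 adjusted over the list alone; 0.000729, adjusted p = 0.0857 with an estimated correlation). One of the higher ones, Mef2c, also a muscle gene, rose by 2.67 ± 0.79 with all libraries and changed sign without floxed replicate b (-0.54, adjusted p = 0.708), and was lost without control c (0.119) or control d (0.109). Gfi1b, one of the lower ones, did not pass without floxed b (0.0597). NK cell genes moved both ways, with 4 of 11 higher and 1 lower (0.18): Gzmb rose by 3.44 ± 0.49 (391 against 36.1 CPM) and Il2rb by 2.81 ± 0.38, and Gzma fell by 1.42 ± 0.18 (516 against 1380). Of 3 tested ILC3 genes 2 rose (3 adjusted over the list alone; 0.000647, 0.033 with an estimated correlation), led by Ahr (2.78 ± 0.29). Immediate early and heat shock genes had 6 of 9 higher (7 adjusted over the list alone; 2.51e-05, 0.0339 with an estimated correlation), with Dusp1 at 2.13 ± 0.23 and Fosb at 2.94 ± 0.53, while Fos and Zfp36 were lost without control d (0.114 and 0.0623). Of 3 B cell markers 2 fell (3 adjusted over the list alone; 0.00293, adjusted p = 0.0584 with an estimated correlation), Vpreb1 by 4.21 ± 0.47. Gamma-delta T cell genes had 2 higher and 2 lower of 8 (0.754), with Tcrg-C1 at 0.85 ± 0.14 and Trdc at -0.82 ± 0.11, and the alpha-beta constant genes did not pass (0.968). The remaining lists were not called: cell division 0.18 with 2 of 17 lower (0 adjusted over the list alone), p53 targets 0.281 with 1 lower, interferon response 0.376 with 1 higher and 2 lower, mast cell markers 0.221 with 2 lower, and myeloid markers 0.754 with 1 higher. Stromal markers had 0.281 with 1 higher and 1 lower, and lung markers 0.933 with 1 lower, where median (1.75) and mean (1.23) are positive and the test points down. The lower cell division genes, Bub1 and Aurkb, did not pass without floxed b (0.511 and 0.44), control c (0.31 and 0.175) or control d (0.0566 and 0.0856). The mean of stromal markers (0.23) and their median (-0.46) also differ in sign.

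The largest positive changes in DN1 on day 7 were in skeletal muscle genes and lay in 1 library. Markers of muscle summed to 8660 CPM in floxed replicate b, against 73.8 in floxed a and 9.58 and 10.2 in controls. Myh4 rose by 10.10 ± 2.22 (1080 against 0.959 CPM), and with it Tnnc2 (9.88), Pvalb (9.59), Ckm (9.32) and Acta1 (8.88). Ttn, with 2 control counts, had a ratio of 2790 (773 to 23100), and Des and Tcap, with 1 each, of 1240 and 805. Xirp2 and Cmya5 had none in controls and were at least 284-fold and 152-fold higher. None passed without floxed b (adjusted p = 0.116 for Des, 0.137 for Cmya5, 0.178 for Ttn, 0.2 for Ckm, 0.258 for Myh4, 0.261 for Tnnc2, 0.316 for Xirp2, 0.366 for Acta1, 0.382 for Pvalb and 0.44 for Tcap). Among the largest negative changes were Mzb1 (-5.55 ± 0.58), Tspan2 (-5.00 ± 0.36), Mpzl2 (-4.96 ± 1.07), Ly6d (-4.70 ± 0.62) and Khdc1a (-4.64 ± 0.35), and the Y-linked Eif2s3y, at least 146-fold lower, Ddx3y and Uty.

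The change of the DN1 genotype difference from day 4 to day 7 subtracts what the cultures differed by before 4-OHT, with n = 2 in each of 4 groups. Maf gained 3.62 ± 0.44 (adjusted p = 5.71e-05), Lmo4 3.16 ± 0.32, Rora 2.73 ± 0.51, Ahr 2.61 ± 0.40 and Id2 2.45 ± 0.29, while Rag1 lost -5.34 ± 0.64, Dntt -5.10 ± 0.57 and Notch1 -2.77 ± 0.27. Gata3 (0.75 ± 0.28, adjusted p = 0.112) and Il13 (3.79 ± 3.13, 0.502) did not pass. In all, 632 genes moved up and 548 down, 1180 together. The lists of recombination genes (8 of 18 down, 11 adjusted over the list alone; camera adjusted p = 1.39e-15, 0.0416 with an estimated correlation), Notch genes (5 of 9 down, 6 adjusted over the list alone; 3.45e-08, 0.00387) and E and Id proteins (5 down and 1 up, 6 and 1 adjusted over the list alone; 4.36e-05, 0.00695) kept their calls with an estimated correlation, the last list holding the targeted Tcf12 and Tcf3, whose fall was made by the design. That of ILC2 transcription factors did not (6 up and 3 down of 13, 9 and 4 adjusted over the list alone; 0.000222, adjusted p = 0.138 with an estimated correlation). The list of ILC2 receptors, called higher on day 4 already, was not called for this change. The number that passed was 629, 578 and 725 without floxed a, control c and control d of day 4, and 3748, 685, 719 and 583 without floxed a, floxed b, control c and control d of day 7. Gzmb (2.68 ± 0.69) was lost without day 7 control d (adjusted p = 0.106), day 4 control d (0.121) or day 7 floxed b (0.0503).

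Control cultures changed between days 4 and 7 without deletion of E2A and HEB. Day 7 cells had also received 4-OHT, which induces the Cre, and had been sorted for tdTomato. Day 4 libraries were unsorted and held stromal RNA. Time in culture cannot be told apart from these differences, so the comparison gives their joint background for both precursors. In DN1 controls Cd3d rose by 2.57 ± 0.28 (162 against 27.1 CPM), Dntt by 2.39 ± 0.38 and Bcl11b by 1.43 ± 0.12, and Id3 fell by 1.79 ± 0.17 (262 against 902 CPM; n = 2 per group). Tcf12 rose by 0.67 ± 0.10. Trp53inp1 rose by 2.74 ± 0.17 and Egr1 fell by 4.54 ± 0.36. Of 15172 genes, 2617 rose and 3265 fell. Of 13 stromal markers 12 fell (camera adjusted p = 2.59e-13, adjusted p = 0.0748 with an estimated correlation), with Fn1 at -6.91 ± 0.36 and Bgn at -6.88 ± 0.50. Of 18 recombination and pre-TCR genes 10 rose (the same adjusted over the list alone; 0.000345, adjusted p = 0.302 with an estimated correlation). Of 8 gamma-delta T cell genes 6 rose (7 adjusted over the list alone; 9.95e-06, adjusted p = 0.0748 with an estimated correlation), and of 17 ILC2 receptors 8 rose, with Il1rl1 at -3.84 ± 0.93 (0.00196, adjusted p = 0.241 with an estimated correlation). Of 10 p53 targets 8 rose and Phlda3 fell (0.000622, adjusted p = 0.0748 with an estimated correlation), and of 9 immediate early genes 8 fell (0.000339, adjusted p = 0.0873 with an estimated correlation).

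In DN3 controls 1834 genes rose and 1966 fell over the same days, 3800 in all, with 2277 without day 4 control c and 2318 and 2372 without day 7 controls c and d. Gata3 rose by 0.98 ± 0.20 (164 against 83.4 CPM), Tnfrsf18 by 2.44 ± 0.36 and Gzmb by 2.77 ± 0.50 (163 against 23.6 CPM; n = 2 per group), and Slc16a3 by 4.80 ± 0.45. Of 10 p53 targets 9 rose (camera adjusted p = 1.73e-11, 0.00169 with an estimated correlation), among them Bbc3 (2.08 ± 0.15) and Zmat3 (1.81 ± 0.15). Of 13 stromal markers 12 fell (2.34e-17, 0.0325 with an estimated correlation), Cxcl12 by 6.00 ± 0.61. Of 17 cell division genes 10 fell (0.00477, adjusted p = 0.148 with an estimated correlation), and of 11 NK cell genes 6 rose (7 adjusted over the list alone; 0.000398, adjusted p = 0.0924 with an estimated correlation). Of 9 interferon response genes 7 rose (8 adjusted over the list alone; 2.86e-05, adjusted p = 0.12 with an estimated correlation), with Irf7 at 3.26 ± 0.55.

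The DN3 cultures on day 4 differed in more genes than the DN1 cultures. Xist was higher in floxed cells (4.89 ± 0.53) and Ddx3y (-4.87 ± 0.40) and Uty (-4.72 ± 0.45) lower. Of autosomal genes, Napsa was lower by -4.23 ± 0.36 (1.4 against 27.5 CPM) and Arhgap9 by -1.60 ± 0.18, and Gdpd3 (3.68 ± 0.39; 29.8 against 2.21 CPM), Rap1gap2 (1.78 ± 0.22) and Aldh2 (1.64 ± 0.15) were higher (n = 2 per group). Rps13-ps1 (1.34 ± 0.10) and Rpl29 (-1.48 ± 0.10), with related copies in the genome, moved as in DN1. In all 67 genes passed (29 higher, 38 lower; 1243 at an unadjusted p under 0.05), with 37 without floxed a, 30 without floxed b, 31 without control c and 41 without control d. Of the 16 genes found in DN1, 13 passed here in the same direction, against 0.0707 by chance, in other libraries. The number by chance takes DN1 and DN3 as independent. The labels do not say whether they share animals, and sex went with genotype in both. Most of the 67 genes stayed different on day 7, 24 of the 29 higher and 35 of the 38 lower. No list member passed, though camera called stromal markers higher (0.00148, adjusted p = 0.614 with an estimated correlation), cell division genes lower (0.00115, adjusted p = 0.281) and early progenitor genes lower (0.0497, adjusted p = 0.614).

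In DN3 cells on day 5, 1 day after 4-OHT, Ptcra fell by 3.19 ± 0.32 (5.57 against 50.8 CPM; adjusted p = 2.56e-06, n = 2 per group), Cdkn1a by 2.24 ± 0.16 (19.3 against 91.2) and Mpzl2 by 3.33 ± 0.64 (18.3 against 185). Ms4a6b rose by 2.82 ± 0.35 (439 against 62.1 CPM), Tbc1d4 by 2.54 ± 0.23, Adgrg5 by 2.90 ± 0.31 and Rora by 2.71 ± 0.47 (29.1 against 4.44). Zbtb16 had no counts in controls and was at least 17.1-fold higher. Gdpd3 (4.89 ± 0.40) and Rap1gap2 (2.56 ± 0.22), already higher on day 4, and Napsa (-3.12 ± 0.33), already lower, stayed so, as did Xist and Y-linked genes. Myof (-3.48 ± 0.45), Ndrg1 (-2.39 ± 0.27) and Tenm1 (-2.38 ± 0.38) fell. In all 692 genes rose and 789 fell, 1481 of 15172, with 449 without floxed replicate b, 720 without control c and 709 without control d.

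Cell division genes fell together in DN3 on day 5: 12 of 17 fell and none rose (13 adjusted over the list alone; camera adjusted p = 1.86e-11, 0.00442 with an estimated correlation), Mcm7 by 0.72 ± 0.10 (457 against 755 CPM) and Mcm5 by 0.64 ± 0.11. Mcm2 and Pcna did not pass without floxed b (adjusted p = 0.221 and 0.153) or control d (0.131 and 0.132). Of 18 recombination and pre-TCR genes 8 fell (the same adjusted over the list alone; 7.63e-07, adjusted p = 0.229 with an estimated correlation), Cd6 by 1.39 ± 0.27, while Rag1 did not pass (-0.73 ± 0.35). In the E protein and Id list 4 of 9 fell (5 adjusted over the list alone; 0.000107, 0.0143 with an estimated correlation), among them Id2 (-1.49 ± 0.21; 37.8 against 106 CPM) and Id3 (-1.28 ± 0.17), and the design fixed part of this call, since Tcf12 and Tcf3 are in the list. Of 13 ILC2 transcription factors 6 rose and 2, Id2 and Gfi1, fell (the same adjusted over the list alone; 0.0172, adjusted p = 0.554 with an estimated correlation). Of 17 ILC2 receptors 3 rose, with Il2ra at 0.77 ± 0.10 (716 against 418 CPM) and Il17rb at 0.86 ± 0.13, and Il7r fell (0.248), the last not passing without floxed b (adjusted p = 0.275), control c (0.058) or control d (0.109). Of 11 NK cell genes 2 rose (4 adjusted over the list alone; 0.00088, adjusted p = 0.15 with an estimated correlation), Gzma by 1.50 ± 0.17 (1920 against 682 CPM). Calls of these lists were lost for Maf, Cd4, Dntt and Nkg7 without floxed b (adjusted p = 0.13, 0.196, 0.353 and 0.104) or control d (0.0753, 0.193, 0.154 and 0.0632), for Maf and Dntt also without control c (0.061 and 0.11) and for Cd4 without floxed a (0.0868). Id1 was lost without floxed a (0.223) or control d (0.387), and Ptgir whichever library was left out (0.0733 to 0.268). Of 10 p53 targets Cdkn1a alone passed (0.017, adjusted p = 0.173 with an estimated correlation). Notch pathway genes were not called (0.736; median 0.07, mean -0.16), and no myeloid marker passed, while Pdgfrb of the stromal markers (1.39 ± 0.18) and Pecam1 of the lung list (0.65 ± 0.14) rose alone.

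On day 7 DN3 cells expressed effector and ILC2 genes and little Rag1. Gzmb rose by 4.18 ± 0.49 (2950 against 163 CPM; adjusted p = 4.48e-06, n = 2 per group), Lgals3 by 4.07 ± 0.52 (844 against 50.5), S1pr1 by 4.38 ± 0.41 (228 against 11.1), Rora by 3.36 ± 0.38 (203 against 19.9) and Icos by 3.15 ± 0.41 (302 against 34.3). Il4 rose by 3.91 ± 0.63 (9.12 against 0.604 CPM) and Il13 by 3.42 ± 0.69 (9.43 against 0.859). Rag1 fell by 6.15 ± 0.47 (7.77 against 530 CPM), Cd4 by 4.70 ± 0.58 and Cd8a by 4.58 ± 0.56. Other large changes were in Homer2 (6.04 ± 0.64), Nt5e (4.98 ± 0.44), Scin (4.70 ± 0.57) and Cd200r1 (3.79 ± 0.55) upward and Myof (-6.05 ± 0.62), Mpzl2 (-5.84 ± 0.84) and Tenm1 (-5.01 ± 0.53) downward, and Fbp1, at least 94.8-fold lower, had no counts left. Fbp1 had passed as lower in floxed DN3 cells on day 4 already, before 4-OHT (-1.94). Dgkeos (-5.64 ± 0.67), an antisense gene, is uncertain, since the strand of the reads is not given. In all 1959 genes rose and 1816 fell, 3775 of 15172, with 2246 without floxed b and 2149 without control d. Of the genes that rose and fell on day 5, 414 and 457 did so on day 7.

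By list, 9 of 13 ILC2 transcription factors rose in DN3 on day 7 and Gfi1 and Ets1 fell (the same numbers adjusted over the list alone; camera adjusted p = 2.7e-05, adjusted p = 0.0809 with an estimated correlation). Maf rose by 2.99 ± 0.33 and Lmo4 by 2.32 ± 0.24, and Zbtb16, with 1 control count, had a ratio of 71.3 (12.3 to 2870). Of 17 receptors 8 rose and Il7r and Ramp1 fell (10 and 2 adjusted over the list alone; 2.69e-05, adjusted p = 0.0809 with an estimated correlation), with Cysltr1 at 3.56 ± 0.40 and Ptgir at 2.70 ± 0.31. Of 4 type 2 cytokines and effectors 3 rose (0.00321, adjusted p = 0.0695 with an estimated correlation), the third being Lta (2.02 ± 0.25). Of 18 recombination and pre-TCR genes 14 fell and none rose (the same adjusted over the list alone; 1.44e-14, adjusted p = 0.06 with an estimated correlation), while Cd3e and Cd247 did not pass. In the E protein and Id list 5 of 9 fell, Id3 by 2.17 ± 0.17 and Tcf4 by 0.98 ± 0.10, and Id2 rose (7.46e-06, 0.00795 with an estimated correlation), the rise of Id2 (0.69 ± 0.20) not passing without floxed b (adjusted p = 0.15) or control d (0.132). Here too the list holds the targeted Tcf12 and Tcf3. Cell division genes had 12 of 17 lower (the same adjusted over the list alone; 3.91e-09, 0.00795 with an estimated correlation), Birc5 by -1.01 ± 0.09 and Ccnb2 by -0.98 ± 0.16. Of these Plk1 did not pass without floxed a (0.216), control c (0.0753) or control d (0.0889), and Bub1 not without floxed b (0.226), control c (0.104) or control d (0.0783).

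Notch pathway genes split in DN3 on day 7, with Notch3 (-2.23 ± 0.31), Notch1 (-1.48 ± 0.19), Tcf7 (-1.16 ± 0.15) and Bcl11b lower and Dtx1 (2.02 ± 0.28), Nrarp and Hes1 higher among 9 (camera adjusted p = 0.232). NK cell genes had 5 of 11 higher (6 adjusted over the list alone; 0.000374, adjusted p = 0.0695 with an estimated correlation), among them Cd160 (2.27 ± 0.25), Nkg7 (1.99 ± 0.27) and Il2rb (1.71 ± 0.35). Immediate early genes had 6 of 9 higher (the same adjusted over the list alone; 0.000128, adjusted p = 0.0695 with an estimated correlation), with Junb at 1.91 ± 0.18. Kit was the 1 early progenitor gene that rose (3.03 ± 0.30; 171 against 21.2 CPM). Ahr rose by 1.82 ± 0.28 (its list was not called, 0.854). Cpa3 rose among 4 mast cell markers (2.08 ± 0.25), Trac fell among the alpha-beta constant genes (-2.33 ± 0.44; 5.1 against 25.6 CPM), and Trbc1 and Trbc2 did not pass. Markers of other cells moved singly: Ctss of the myeloid list and Pdgfrb of the stromal list rose and Ebf1 of the B cell list fell, and no lung marker passed.

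**Figure D2:**
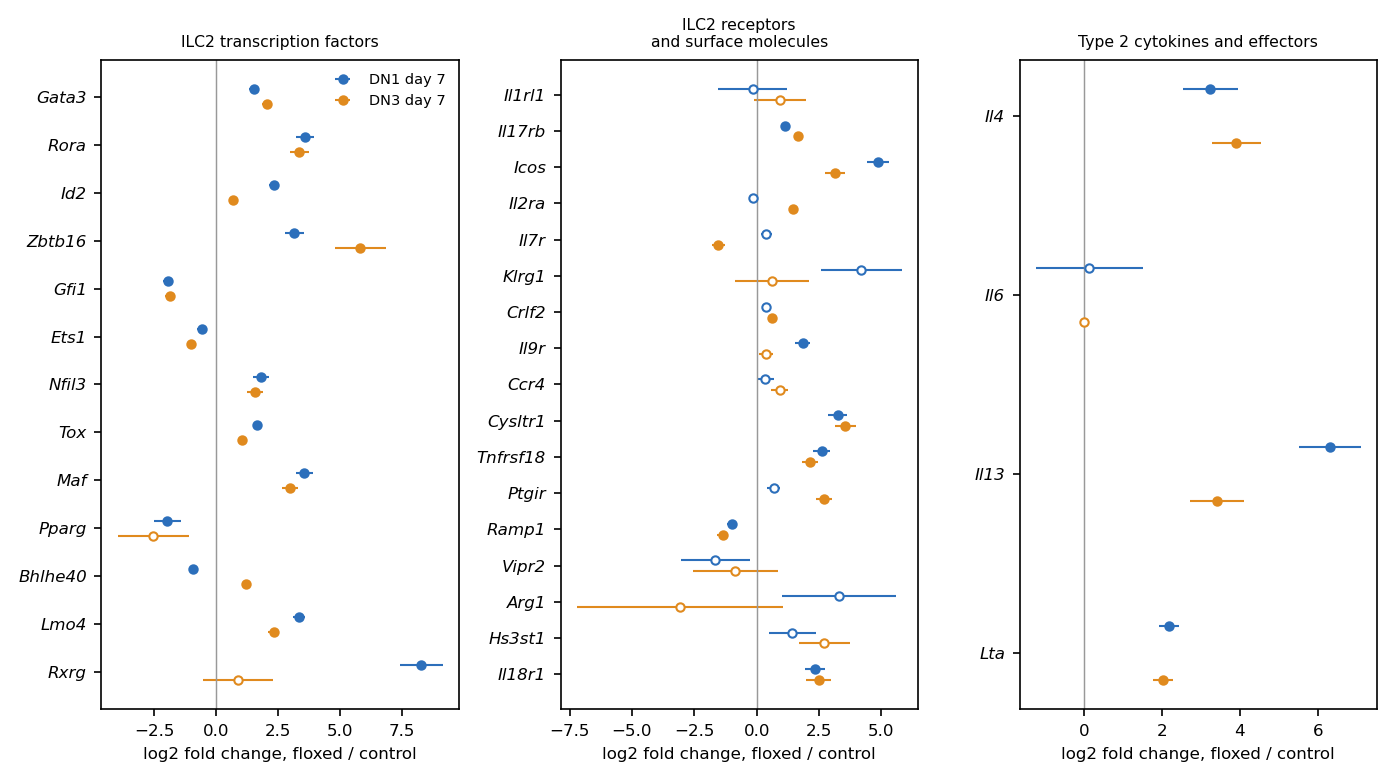
Log2 fold changes (floxed / control, bars are standard errors) of 3 ILC2 gene lists in DN1 (blue) and DN3 (orange) on day 7, n = 2 per group; filled points passed at an adjusted p under 0.05 (Icos: 4.87 in DN1, 3.15 in DN3).

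The change of the DN3 genotype difference from day 4 to day 7 gave 913 genes up and 953 down, 1866 in all (n = 2 in each of 4 groups). Rora gained 3.12 ± 0.58, Icos 3.91 ± 0.64, Gzmb 4.55 ± 0.70 and Il18r1 4.21 ± 1.30, and Rag1 lost -5.99 ± 0.57, Id3 -2.36 ± 0.24 and Notch3 -2.47 ± 0.41. Zbtb16 (5.39 ± 1.59) did not pass without day 4 control d (3.40, adjusted p = 0.575), day 4 floxed a (0.0639) or b (0.0594) or day 7 floxed a (0.0748), control c (0.0504) or control d (0.163), and Cysltr1 (5.25 ± 1.04) not without day 4 control d (0.178). Recombination genes had 11 of 18 down (12 adjusted over the list alone; camera adjusted p = 7.84e-14, adjusted p = 0.054 with an estimated correlation), and E and Id proteins, a list with the targeted Tcf12 and Tcf3 in it, 5 of 9 down and 1 up (1.93e-05, 0.012 with an estimated correlation). ILC2 transcription factors had 8 of 13 up and 2 down (9 and 2 adjusted over the list alone; 9.82e-05, adjusted p = 0.15 with an estimated correlation) and cell division genes 7 of 17 down (9 adjusted over the list alone; 6.49e-05, adjusted p = 0.054 with an estimated correlation). The total was 1123, 1196 and 1171 without floxed b, control c and control d of day 4, and 1075 and 984 without floxed b and control d of day 7.

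The DN1 and DN3 responses were then set against each other. On day 7, 876 genes rose in both and 626 fell in both, against 239 and 187 by chance, while 43 rose in DN1 and fell in DN3 and 57 did the reverse (221 and 202 by chance). The comparisons share no libraries, and across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.29. The numbers by chance take DN1 and DN3 as independent, though the labels do not say whether they share animals. On day 5 the shared numbers were 160 and 126 (17.7 and 19.4 by chance). A difference between the responses passed for 207 genes on day 5 and 1182 on day 7 (n = 2 in each of 4 groups). On day 5 Id3 rose in DN1 and fell in DN3 (difference 2.39 ± 0.24, adjusted p = 3.36e-05), Il2ra rose in DN3 only (-0.96 ± 0.14), and Gzma, which rose in DN3, did not pass in DN1 (-0.30 ± 0.17, adjusted p = 0.393; difference -1.80 ± 0.25). Cell division genes fell in DN3 and not in DN1, as camera had them lean on day 4 before 4-OHT (higher in DN1, lower in DN3), with 3 of 17 different (8 adjusted over the list alone; camera adjusted p = 3.52e-11, 0.00515 with an estimated correlation), Mki67 by 0.92 ± 0.15. On day 7 Gzma differed by -2.64 ± 0.25, Id2 by 1.65 ± 0.28, Bhlhe40 by -2.16 ± 0.22, Il2ra by -1.59 ± 0.14 and Kit by -2.55 ± 0.40. Nrarp (-2.40 ± 0.29) and Hes1 (-2.22 ± 0.32) fell in DN1 and rose in DN3. The Notch list was called (3 lower and 1 higher of 9, 5 and 2 adjusted over the list alone; 0.0102, adjusted p = 0.0826 with an estimated correlation), as were cell division genes (8 of 17 higher in DN1, 9 adjusted over the list alone; 6.63e-06, adjusted p = 0.0676 with an estimated correlation). The day 5 total was 78, 56 and 59 without DN1 floxed b, control c and control d, and 110, 70, 86 and 89 without DN3 floxed a, floxed b, control c and control d. The day 7 total was 3150, 648 and 637 without DN1 floxed a, control c and control d, and 601, 763 and 497 without DN3 floxed b, control c and control d.

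**Figure D3:**
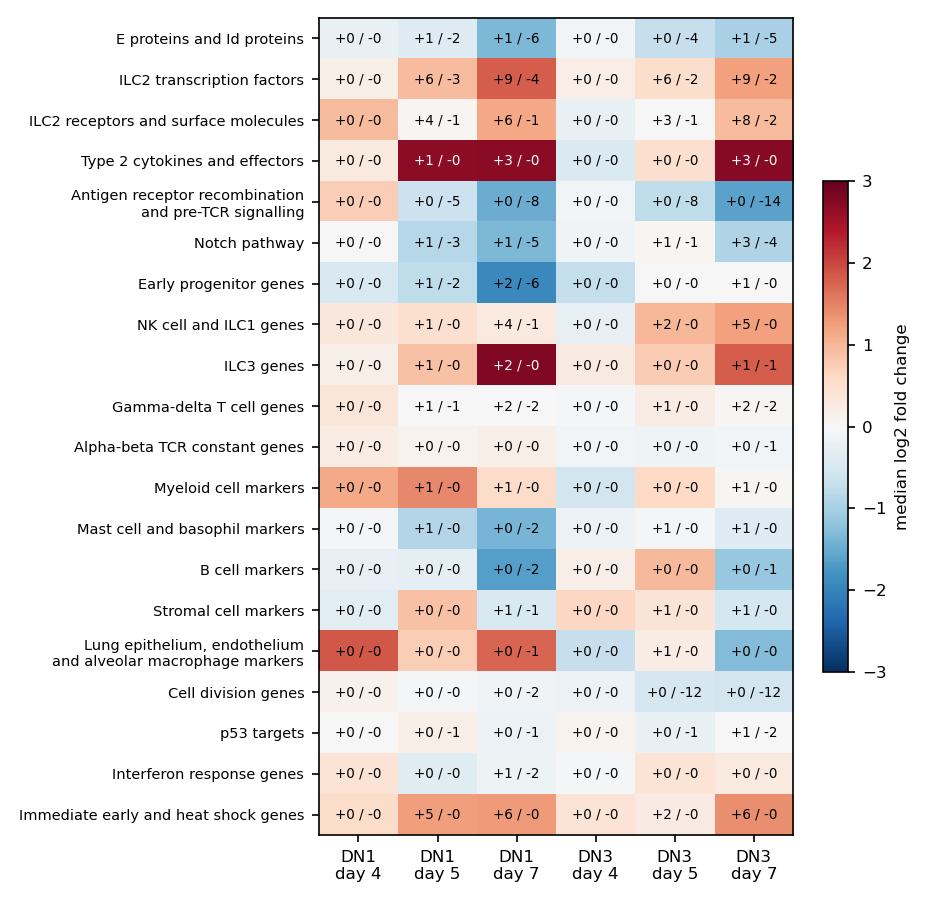
Median log2 fold change (floxed / control, color) of the genes of each list in DN1 and DN3 on days 4, 5 and 7, n = 2 per group; the text in each cell gives how many genes passed higher and lower (recombination genes in DN3 on day 7: 0 higher, 14 lower).

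Control DN1 and DN3 cells on day 4 differed by stage, with 3765 genes higher and 2265 lower in DN1 (6030 of 15172; n = 2 per group). All 18 recombination and pre-TCR genes were lower in DN1 (camera adjusted p = 4.4e-24, 0.0153 with an estimated correlation), Rag1 by -3.93 ± 0.40 (21.9 against 333 CPM). Of 13 early progenitor genes 11 were higher (8.06e-07, 0.0292 with an estimated correlation), Bcl11a by 4.94 ± 0.43, Lyl1 by 4.51 ± 0.37 and Cd34 by 4.38 ± 0.52. Of 17 cell division genes 16 were lower (7.62e-14, 0.00252 with an estimated correlation), Mki67 by -1.41 ± 0.11, and 3 of 4 mast cell markers were higher (0.00139, 0.0314 with an estimated correlation), with Cpa3 at 4.18 ± 0.28. E proteins and Id proteins were called higher (6 higher and 1 lower of 9, 7 and 1 adjusted over the list alone; 0.033, adjusted p = 0.105 with an estimated correlation), Id1 by 2.39 ± 0.21, while Tcf3 did not pass (-0.54 ± 0.35). Bcl11b (-2.25 ± 0.13), Tcf7 (-1.90) and Ets1 (-2.50 ± 0.18) were lower. Of 13 stromal markers 11 were higher in DN1 (12 adjusted over the list alone; 1.44e-05, adjusted p = 0.191 with an estimated correlation), Fn1 by 2.33 ± 0.28, so stromal RNA moved with this comparison. Among the largest differences were Fgf3 (6.21 ± 0.75), Hbb-bt (5.92 ± 0.67), Nrgn (5.16 ± 0.41), Cd2 (-5.24 ± 0.43) and Ikzf3 (-5.22 ± 0.59). H2-Q1 and H2-Q2, paralogs, are uncertain.

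ILC2 taken directly from dKO thymus were compared with the floxed cultures of day 7, which asks how near the cultured cells come to them. Of 16391 genes tested, 12079 differed from DN1 (5506 higher in ILC2) and 11772 from DN3 (5406 higher), n = 2 per group. The kind of library and the sex differed too: Xist had 0.176 and 0.208 CPM in the ILC2 and Y-linked genes 298 and 362, against 1280 to 1880 and 0.508 to 2.53 in the floxed cultures. Mitochondrial rRNA took 54.8 and 52% of the counts in ILC2, processed pseudogenes took 0.172 and 0.203%, and histone genes such as Hist1h2ap had no counts (at least 1060-fold and 931-fold lower). Changes followed exonic length (Spearman 0.371 and 0.387 over 12678 protein-coding genes, which are not independent replicates; median change -1.52 and -1.49 in the shortest tertile, 0.67 and 0.73 in the longest). RLE scaling moved all genes up by a median of 0.30 and 0.33, Tcf12 against DN1 from 1.38 to 1.68. Il1rl1, the receptor for IL-33, was higher in ILC2 by 10.60 ± 0.73 than in DN1 cells (426 against 0.272 CPM) and by 8.85 ± 0.64 than in DN3 cells. Pparg was higher by 4.35 ± 0.54 than in DN1 cells and had a ratio of 339 (60 to 13500) to DN3 cells. Gzmb had no counts in ILC2 and was at least 798-fold and 6000-fold lower, Il13 had 1 count (ratios of 152, 27 to 6000, and 60.3, 10.6 to 2400, lower), and Id3 had none (at least 177-fold and 142-fold lower). Id2 was lower by -4.39 ± 0.34 and -3.24 ± 0.33, while Rora (-0.70 ± 0.34, adjusted p = 0.0675, against DN1) and Icos (-0.78 ± 0.37, 0.0643) did not pass.

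No list was called by camera in either thymic comparison (lowest adjusted p 0.164 against DN1 and 0.103 against DN3, p53 targets). Camera weighs a list against the other genes, most of which differed here, so a missing call does not show a level list. Members of the ILC2 and recombination lists moved both ways. Of 18 ILC2 receptors 10 were higher and 2 lower than in DN1 cells, and 10 and 4 than in DN3 cells, with Tnfrsf18 lower (-5.91 ± 0.45 and -6.61 ± 0.46). Of 13 ILC2 transcription factors 3 were higher and 9 lower than in DN1 cells, and 3 and 6 than in DN3 cells. Of 18 recombination and pre-TCR genes 7 were higher than in DN1 cells, among them Rag2 (7.61 ± 0.53; 105 against 0.511 CPM), Cd3e (5.37 ± 0.38) and Themis (5.00 ± 0.37), and 2 were lower, against 8 and 8 in the DN3 comparison. Tcrg-C2 was higher by 2.77 ± 0.16 (2170 against 318 CPM) and 1.97 ± 0.16. Mki67 was higher by 4.79 ± 0.20 (5870 against 212 CPM) and 5.01 ± 0.20, while Birc5, a short gene of the same list, was lower by -3.79 ± 0.12 and -3.58 ± 0.12. Of NK cell genes 8 and 9 of 12 were lower and none higher. Fos had no counts in ILC2 (at least 176-fold and 257-fold lower), and Bbc3 none (at least 171-fold and 139-fold lower). Acta1 (no counts in ILC2) did not pass against DN1 without DN1 floxed replicate b (adjusted p = 0.0608), and Trbc1 (0.61) not without thymic replicate 1 (0.14, adjusted p = 0.26).

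A set of 200 genes higher and a set of 200 genes lower in thymic ILC2 than in day 4 controls was tested in the floxed against control comparisons. Of 8 tests 2 passed, both on day 5: the lower set in DN1 (camera adjusted p = 0.00418) and the higher set in DN3 (0.0137), and none passed with an estimated correlation. On day 7 none passed (0.65, 0.647, 0.647 and 0.74). With protein-coding genes only, the lower set was called higher in DN1 on day 7 (camera adjusted p = 0.0469), away from thymic ILC2. The other 4 that passed so, all on day 5, pointed toward thymic ILC2 (higher set 0.0273 in DN1 and 0.000999 in DN3, lower set 0.000999 and 8.57e-06). The sets rest on a comparison of library kinds, as above. Day 4 controls also held stromal RNA, with 2750 to 13800 CPM of markers against 25.8 and 35.7 in thymic ILC2. The lower set can therefore hold stromal genes, which was not checked, and its fall need not be a move toward thymic ILC2.

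Lung ILC2 of dKO mice were compared with those of Id1 transgenic mice, 2 ways of lowering E protein activity (n = 2 and 3). Id1 had 59.3 CPM in Id1 libraries and 1 count in dKO (ratio 488, 87.4 to 19300). Areg was higher in dKO by 4.99 ± 0.42 (421 against 13.3 CPM; adjusted p = 0.000986) and Calca by 3.38 ± 0.33 (177 against 17). Ccr8 was lower by -4.38 ± 0.45 (3.6 against 76.7 CPM), Ccr4 by -3.48 ± 0.39, Kit by -3.45 ± 0.44 (38.6 against 419), Fosb by -3.02 ± 0.38 and Trim12a by -4.46 ± 0.54. Il1rl1 did not differ past the threshold (-0.12 ± 0.39; 1400 against 1520 CPM), nor did Tcf12 (-0.71 ± 0.33, adjusted p = 0.162).

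In all 2790 genes were higher in dKO lung and 709 lower, 3499 of 19371, so 79.7% were higher, and the median of all genes was 0.17 (RLE scaling moved genes up by a median of 0.21). The total was 6396 with DESeq2 and 2142 with protein-coding genes only, and at a mean CPM of at least 20 it was 1002, of which 39.5% were higher in dKO. Leaving out dKO replicate 1 gave 5774, dKO replicate 3 gave 183, Id1 replicate 1 gave 1785 and Id1 replicate 3 gave 2050. The largest changes lay in genes with no counts in Id1, such as Olfr771 (at least 373-fold) and Vgll3 (at least 350-fold). Chemosensory receptor genes summed to 3070 and 7970 CPM in dKO libraries (1143 and 1461 genes detected), against 507 to 729 CPM (474 to 637) in Id1. The Gm10800 family of satellite-like genes took 7.22 and 48.2% of dKO counts against 0.504 to 3.16%. Of 19 ILC2 receptors 5 were lower and none higher (6 adjusted over the list alone; camera adjusted p = 0.000307, adjusted p = 0.622 with an estimated correlation), and of 5 E and Id proteins 2 were lower (0.0058, adjusted p = 0.622 with an estimated correlation), Id2 and Id1, the transgene of the Id1 group, so the design fixed part of this call. Of 11 stromal markers 2 were higher (5 adjusted over the list alone; 0.0159, adjusted p = 0.622 with an estimated correlation). Markers of other cells passed too, without a list call: Klrd1 (5.19 ± 1.06), Gzma (4.31 ± 1.09) and Klrk1 (2.20 ± 0.65) of NK cells, Hdc (3.17 ± 0.69) of mast cells and Scgb1a1 (4.54 ± 1.15) of lung epithelium were higher, and the NK cell gene Il2rb (-1.68 ± 0.43) and the mast cell gene Cpa3 (-2.49 ± 0.55) lower. Also higher were the T cell gene Cd8b1 (4.37 ± 1.33) and the progenitor gene Mef2c (3.62 ± 0.94), and, against 1 to 3 counts in Id1, Pax5 of B cells (ratio 250, 67.9 to 2090), Cd8a (119, 20 to 4860), Cd34 (54.1, 13.7 to 468) and Gata2 of mast cells (39.8, 12.5 to 203). Of 13 ILC2 transcription factors 3 were lower (0.0501) and of 9 type 2 cytokines and effectors Areg and Calca were higher (0.0572). Among gamma-delta genes Tcrg-C2 was higher by 2.70 ± 0.44 (731 against 113 CPM). Of 37 calls of genes named by the rule, 23 were lost without at least 1 library: without dKO replicate 3 there was no call for Rora (-1.42, adjusted p = 0.113), Arg1 (0.156), Klrd1 (0.188), Klrk1 (0.233), Pax5 (0.0537), Hdc (0.0567), Cpa3 (0.07), Cd8a (0.158), Mef2c (0.0777), Trim34a (0.0654), Trim30d (0.0579), Tmem176a (0.0777) or Tagln2 (0.0748), and without dKO replicate 1 none for Nmur1 (0.0705), Gzma (0.0923), Trdc (0.122), Scgb1a1 (0.116) or Col1a1 (0.0937). Without Id1 replicate 1 the call was lost for Bhlhe40 (0.0841), without Id1 replicate 2 for Il2rb (0.0554) and without Id1 replicate 3 for Id2 (0.0847).

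**Figure D4:**
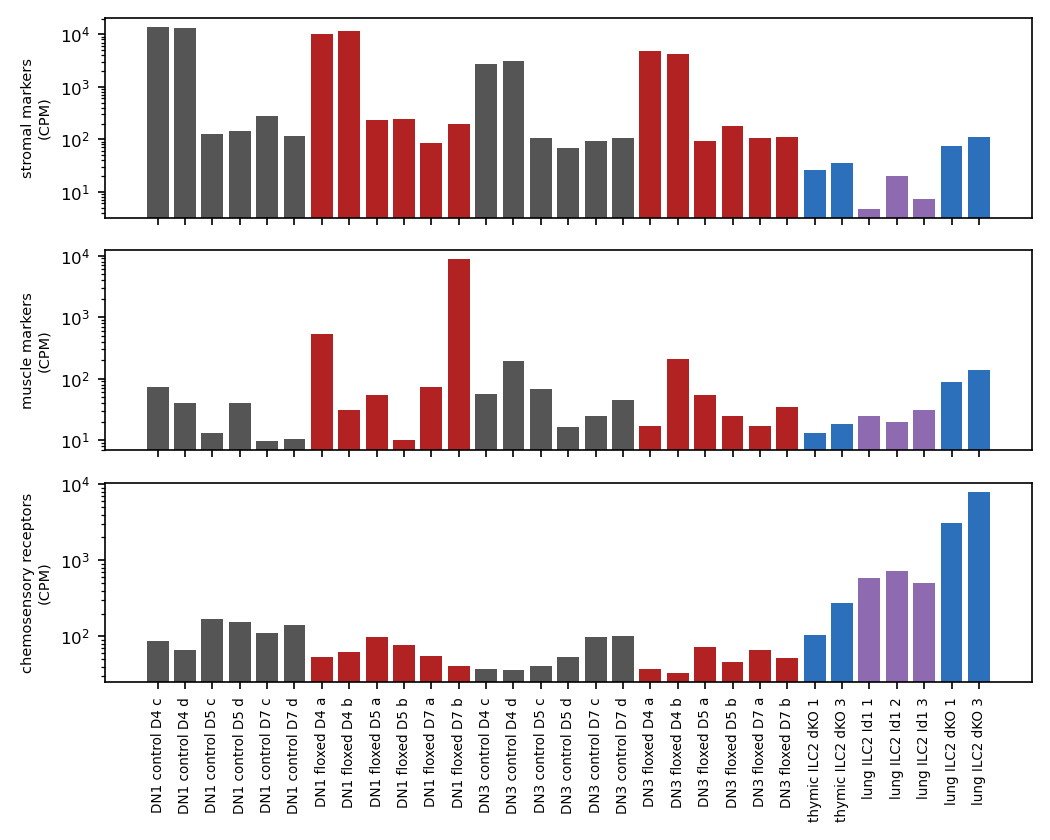
CPM (log scale) of stromal markers (top), muscle markers (middle) and chemosensory receptor genes (bottom) in each of 31 libraries; each bar is 1 library, floxed in red, control in grey, dKO ILC2 in blue and Id1 ILC2 in violet (muscle markers in DN1 floxed D7 b: 8660 CPM).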

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

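The tests of X and Y transcripts, of strain variants and of deletion before 4-OHT, and the test of a response to deletion for the muscle genes, were chosen only after the result was seen. All values in the next 4 paragraphs stand here for 1 reason, a tested difference between groups: the genotype effect on day 7 against the same effect on day 4, or the effect in DN1 against the effect in DN3 (interaction terms in edgeR, n = 2 in each of 4 groups).

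In DN1 the genotype effect differed between days 4 and 7 for 1180 genes. The lists of recombination and pre-TCR genes (camera adjusted p = 1.39e-15, 0.0416 with an estimated correlation), the Notch pathway (3.45e-08, 0.00387), E and Id proteins (4.36e-05, 0.00695) and ILC3 genes (0.00195, 0.0416) were called under both. The E and Id list holds the deleted Tcf12 and Tcf3, so the design fixed part of its call. Those of ILC2 transcription factors (0.000222), immediate early genes (0.0056), cell division genes (0.0111), type 2 cytokines (0.0339) and mast cell markers (0.0457) were not called with an estimated correlation (adjusted p = 0.138 for each), nor were B cell markers (0.00861, then 0.106), early progenitor genes (0.00867, then 0.171) and gamma-delta T cell genes (0.0285, then 0.263). Among named genes the effect moved down for Rag1 (-5.34), Dntt (-5.10), Cd3g (-4.46), Lyl1 (-3.17), Notch1 (-2.77), Gzma (-1.78) and Id3 (-1.29). It moved up for Tnfrsf18 (1.67), Lta (2.31), Id2 (2.45), Ahr (2.61), Gzmb (2.68), Rora (2.73), Lmo4 (3.16), Icos (3.40) and Maf (3.62). Tnfrsf18 did not pass without day 7 floxed b (0.89, adjusted p = 0.298), control c (0.0957) or control d (0.148), or without day 4 floxed b (0.172), control c (0.211) or control d (0.0715), and Gzmb not without day 4 control d (0.121), day 7 floxed b (0.0503) or day 7 control d (0.106).

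In DN3 it differed for 1866 genes. E and Id proteins, again with the 2 deleted genes in the list, were called (camera adjusted p = 1.93e-05, 0.012 with an estimated correlation). Recombination genes (7.84e-14), NK cell genes (0.000114) and cell division genes (6.49e-05) were not called with an estimated correlation (adjusted p = 0.054 for each), nor were ILC2 receptors (2.58e-05, then 0.128), ILC2 transcription factors (9.82e-05, then 0.15), immediate early genes (0.00326, then 0.15) and type 2 cytokines (0.0395, then 0.156). The effect moved down for Rag1 (-5.99), Cd4 (-4.69), Notch3 (-2.47), Id3 (-2.36), Birc5 (-1.06) and Mki67 (-0.91), and up for Dtx1 (1.94), Maf (2.31), Lta (2.65), Rora (3.12), Icos (3.91), Kit (4.34), Gzmb (4.55), Cysltr1 (5.25) and Zbtb16 (5.39). Zbtb16 did not pass without day 4 floxed a (adjusted p = 0.0639), floxed b (0.0594) or control d (0.575), or without day 7 floxed a (0.0748), control c (0.0504) or control d (0.163), and Cysltr1 not without day 4 control d (0.178).

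Between DN1 and DN3 the effect differed for 207 genes on day 5. Cell division genes were called (camera adjusted p = 3.52e-11, 0.00515 with an estimated correlation), and p53 targets (0.0134, then 0.203) and immediate early genes (0.0274, then 0.322) were not called with an estimated correlation. Lower in DN1 were Adgrg5 (-2.53), Tbc1d4 (-2.44), Khdc1a (-1.98), Gzma (-1.80), Cd3g (-1.51), Pdgfrb (-1.50), Bhlhe40 (-1.07), Il2ra (-0.96) and Tcrg-C2 (-0.96). Higher were Top2a (0.64), Mcm7 (0.79), Mki67 (0.92), Cdkn1a (1.43), Dusp1 (1.50), Id2 (1.53), Cd6 (1.75), Napsa (1.99), whose difference was there on day 4, and Id3 (2.39). Calls of 6 genes rested on single libraries of day 5. Cd6 did not pass whichever of the 8 was left out (adjusted p = 0.0505 to 0.23), and Cd3g passed only without DN1 floxed b (0.0507 to 0.147 otherwise). Id2 and Dusp1 passed only without DN1 floxed a or DN3 control d (at most 0.0853 and 0.197 otherwise) and Bhlhe40 only without DN1 floxed b or DN3 control d (at most 0.111). Top2a did not pass without DN1 floxed b (0.0524), DN1 control d (0.0693) or DN3 floxed b (0.0651).

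On day 7 it differed for 1182 genes. Cell division genes (camera adjusted p = 6.63e-06, then 0.0676), the Notch pathway (0.0102) and ILC3 genes (0.0102) were not called with an estimated correlation (adjusted p = 0.0826 for the last 2). Lower in DN1 were Scin (-5.76), Vpreb1 (-3.08), Cd3g (-2.84), Gzma (-2.64), Kit (-2.55), Nrarp (-2.40), S1pr1 (-2.36), Hes1 (-2.22), Bhlhe40 (-2.16), Khdc1a (-2.14), Ptgir (-2.02), Cpa3 (-1.77), Nkg7 (-1.69), Il2ra (-1.59), Notch1 (-1.29), Junb (-1.09) and Trdc (-0.96). Higher were Birc5 (0.92), Mki67 (0.92), Tcf7 (0.95), Ccnb2 (1.08), Il9r (1.47), Id2 (1.65), Il7r (1.91), Trac (2.56), Ptcra (2.84), Cd4 (4.69) and the muscle gene Myh4 (10.94). Il9r did not pass without DN1 control c (adjusted p = 0.105) or d (0.067) or any DN3 library (0.0577 to 0.0885), Ptcra not without DN1 floxed b (0.0935) or DN3 floxed b (0.059), Tcf7 not without DN3 floxed b (0.0681), and Nkg7 (0.0556) and Junb (0.0813) not without DN3 control d.

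The first pattern weighed is the genes that differed between floxed and control cultures on day 4, before 4-OHT. X and Y transcripts of cultures that differ in sex made up 8.96% of the DN3 calls, which argues against them as the whole of it. Deletion of Tcf12 in most cells before 4-OHT is argued against in DN3. Tcf12 changed there by -0.07 (-0.0705 before rounding, standard error 0.0997), where 2 standard errors below it (-0.27) stay above 0.5 of the day 7 change (-0.83). Tcf3 was not tested in this way. On day 4 it had 90.5 and 49.9 CPM in DN3 floxed a and b, against 86.2 and 101 in controls. In DN1 it had 64.5 and 45.4 CPM in floxed a and b, against 62.9 and 66.7. Early loss of Tcf3 in replicate b stays open. Strain variants of the floxed line could not be told from other explanations: 11 of 60 autosomal calls lay within 1 Mb of another, where the median of 10000 draws of 60 tested genes was 6 (permutation p = 0.0617, and 0.0722 with draws from day 7 calls). These draws did not ask where the targeted genes lie. Named outside the rule, Myzap (-6.03 on day 4, -5.62 on day 7) and Mns1 (-1.07 and -1.53) lie on either side of Tcf12 on chromosome 9. Myzap ends at 71592360 and Mns1 starts at 72438011, with Tcf12 at 71842688 to 72111871. Whether their changes come from DNA carried with the floxed allele was not tested. Sex of the animals, acting on autosomal genes, stays open as untested.

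The second pattern is the skeletal muscle transcripts in DN1 floxed day 7 replicate b. A response to deletion is argued against by the other 3 floxed libraries of day 7, which held at most 73.8 CPM of muscle markers against 8660. RNA of skeletal muscle in this library stays a candidate explanation. The 12 markers ranked there as in DN1 floxed day 4 replicate a, picked as the library with the next highest sum (521 CPM). The Spearman correlation was 0.956 (permutation p = 1e-05, the smallest that 100000 permutations can give). Any source with a muscle-like profile would rank the markers alike, so the ranks do not tell where the transcripts came from. How muscle RNA could have passed a tdTomato sort was not tested.

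The third pattern is the genes higher in lung dKO than in lung Id1 ILC2 and near 0 in Id1. None of the explanations tried could be settled. For the Gm10800 family and mitochondrial rRNA taking up counts, 2673 genes were higher without them and 2790 with them. TMM trims such genes anyway, and the others moved by a median of 0.06, too little to decide. Reads of genomic DNA and expression of more genes cannot be told apart: over 2179 genes with no count in the cultures the ratio of X to autosomal counts per exonic kb was 0.588 (0.374 to 0.891) in dKO replicate 1, 1.02 (0.684 to 1.42) in dKO replicate 3 and 0.374 to 0.825 in Id1, where DNA of males would give a value well under 1 and expression about 1. The interval of dKO replicate 1 lies under 1 and that of dKO replicate 3 holds 1. These 2 intervals overlap, so the 2 libraries are not shown to differ. In Id1 replicates 1 and 3 the intervals also lay under 1 (upper bounds 0.736 and 0.898). That of Id1 replicate 2 held 1 (0.372 to 1.48). A value under 1 was thus not particular to dKO, and that expression gives about 1 was assumed. The counts in the 2179 genes followed exonic length at a Spearman correlation of 0.341 and 0.402 in dKO and 0.156 to 0.223 in Id1. These genes are not independent replicates. The 2 transgenic designs stay open as a biological difference that was not tested on its own.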

How the results depend on the processing

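The tests without X and Y genes, without day 4 libraries, without mitochondrial rRNA and Gm10800 family genes, with protein-coding genes only, with a mean CPM of at least 20 and with a day 5 reference were chosen only after the result was seen. With RLE scaling and without X and Y genes the 16 and 10 gene totals they covered stayed within 1.5 times, and so did the 3 of lung and thymic ILC2 without mitochondrial rRNA and Gm10800 genes.

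DESeq2 gave 45 genes for DN1 day 4, 355 for DN1 against DN3 on day 5 and 6396 for the lung. With no filter the totals were 229 for DN1 day 4, 257 for DN3 day 4, 1882 for the DN1 change, 536 for DN1 against DN3 on day 5 and 1900 on day 7. Fits of the compared libraries alone gave 38 for DN1 day 4, 798 for DN1 day 7, 421 for the DN1 change and 369 for DN1 against DN3 on day 7. Without day 4 libraries DN1 against DN3 on day 5 gave 133, and the lung gave 2142 with protein-coding genes only and 1002 at a mean CPM of at least 20, where fewer genes were tested. The cause of the other shifts was not tested.

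A further threshold of 1 on the log2 change, which can only remove genes, left 10, 371 and 1639 for DN1 on days 4, 5 and 7, 782 for the DN1 change and 3491 for DN1 controls. In DN3 it left 43, 502, 1627, 1091 and 1982, and for DN1 against DN3 130 and 711 on days 5 and 7 and 3483 for controls.

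Leaving out 1 library at a time gave 8 to 38 genes for DN1 day 4, 225 to 685 for day 5, 1688 to 5803 for day 7, 578 to 3748 for the change and 4401 to 4590 for controls. In DN3 it gave 30 to 41, 449 to 1203, 2149 to 2878, 984 to 1744 and 2277 to 2561. DN1 against DN3 gave 56 to 149 on day 5, 497 to 3150 on day 7 and 4145 to 4549 for controls, thymic ILC2 11458 to 12463 against DN1 and 10929 to 11599 against DN3, and the lung 183 to 5774.

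Of 94 list calls 24 passed with an estimated correlation, and fry kept 80 and called 133. Of 8 tests of thymic ILC2 genes 2 passed, both on day 5, with 0 under an estimated correlation, 0 with fry and the same 2 with 100 genes. With protein-coding genes 5 of 8 tests passed, both of these among them, and 1, the lower set in DN1 on day 7, pointed away from thymic ILC2. A day 5 reference was tried for day 7 alone and gave 0 of 4, where none of the 4 had passed before. The E and Id list lost its call with an estimated correlation in DN1 on day 5 (adjusted p = 0.155), between DN1 and DN3 controls (0.105) and in the lung (0.622). Tcf3 was lost with DESeq2 in the DN3 change (-1.59, adjusted p = 0.0676) and with RLE scaling between thymic ILC2 and DN3 (-1.04).

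If replicate letters paired the libraries, a replicate block would give 1264 genes for the DN1 change and 3159 for the lung, and none of 6 totals moved past 1.5 times. Deviations from the group mean correlated at -0.237 to 0.232 over 15 pairs of floxed groups, 0.118 to 0.135 over the 3 among DN3 groups, and at -0.0506 to 0.0948 over 15 of control groups. Tcf3 was lower in b than in a in all 6 floxed groups, seen after the fact, so letters a and b may mark something shared, which a block moving none of these totals leaves open. Named genes, Tcf3 and Tcf12 not counted, gave 428 pairs of a gene and a comparison, some of them not called in the main fit. With DESeq2 all 428 stayed called or uncalled as they were. A call was lost in 29 of 387 pairs when the compared libraries were fitted alone. It was lost in 8 of 222 pairs without day 4 libraries and in 5 of 143 with the block. The sign of 1 called gene turned, that of Mef2c in DN1 on day 7 without floxed replicate b (-0.54). At the smallest library total of 3695522 counts, 1 CPM is under 4 reads.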

Other observations

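The tests of shared day 4 calls and of X and Y genes were chosen only after the result was seen. Of 16 DN1 day 4 calls 13 were shared with DN3 (0.0707 by chance), and of the autosomal ones 10 of 13 (0.0535 by chance). Both numbers by chance take DN1 and DN3 as independent, though the labels do not say whether they share animals. Genes on X and Y made up 18.8, 3.94 and 3.25% of the DN1 calls on days 4, 5 and 7. In DN3 they made up 8.96, 3.44 and 3.23%. Of the 15172 tested genes 527 lay on X and 8 on Y. On days 5 and 7 X genes passed slightly less often than genes outside X and Y. On day 7 it was 19.9 against 22.6% in DN1 and 22 against 25% in DN3.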
